A study of Mus musculus with 14 samples.

How the data were processed

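Ovaries of mouse embryos were profiled on 14 Affymetrix arrays. Per the labels' protocols, pregnant females were given tamoxifen on embryonic days 11.5 and 12.5 (2 mg for every 10 g of weight), and fetal ovaries were frozen at E14.5 or E16.5. Tamoxifen activates the WT1-CreERT2 recombinase, which deletes the floxed Coup-tfII gene (symbol Nr2f2), a nuclear receptor of the COUP-TF family. There were 3 control and 3 knockout arrays at E14.5 and 4 control and 4 knockout arrays at E16.5, which the labels call biological replicates. The genotype behind the word control, including whether Cre was present, is not given in the sources used here. The strain background was mixed. Per the labels' protocols, RNA was isolated with a PicoPure kit, and biotin-labelled RNA was made with the Affymetrix 3' IVT Express kit.

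The deposited values are linear probe set intensity values made with MAS5 in Affymetrix Expression Console, per the submitters' processing notes; versions are not given in the sources used here. The trimmed mean of every array, leaving out 2% at each end, was 500, so each array had been scaled to that target. Scaling to a common mean removes any global difference in RNA amount between arrays. The number of arrays limits the precision.

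Intensities were taken as log2(signal + 16), with no further normalization between arrays. A fold change on this scale understates the change of dim genes. Of 45037 probe sets other than controls, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 had none listed; of the first kind, 34741 were found by gene ID in RefSeq gene names (GRCm38.p6), which changed no symbol. Each of 18193 genes was represented by its probe set with the highest mean over the 14 arrays. Genes whose mean lay above the 40th percentile of all probe sets other than controls (signal of about 62.0) were tested, which left 12406 genes. Genes without a probe set of their own in the annotation were not analysed here.

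A linear model with 4 groups was fitted to all 14 arrays with limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3, with the R package data.table (version 1.17.8). Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The comparisons were knockout against control at each stage, E16.5 against E14.5 within each genotype, and the difference of the knockout effect between stages. Of 30 gene lists, the 25 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

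The groups, tests, gene lists, main alternatives and the rule for named genes were chosen before the data were examined. The rule takes Nr2f2 and Wt1, the 10 highest and 10 lowest fold changes past the threshold whose knockout arrays lie all above or all below the controls, leaving out clone and predicted-model symbols, and up to 4 members past the threshold of each list, or up to 2 as values where none passed. Of these, the text gives the leading ones. For the stage comparison in controls it takes 6 in each direction and up to 3 members per list, and for the difference between stages the 6 smallest p. Genes named outside it are said to be so.

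The steps were tested on simulated data built from the real means and spreads of the 12406 genes, with 200 genes changed per simulation in 5 simulations. For knockout against control at E14.5, 32.8% of genes changed 1.5-fold, 69.3% of those changed 2-fold and 91.8% of those changed 3-fold were recovered, and 5.29% of calls were false. For knockout against control at E16.5 the shares were 43.0%, 83.9% and 94.9%, and 5.02% of calls were false. In each comparison camera found the raised list in 5 of 5 simulations and called 0 of 120 unchanged lists. These simulations hold independent genes and no array effects.

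Alternatives changed the pseudocount, the scaling, the filter, the choice of probe set, the spread model and the threshold, left out each array in turn, or used the replicate number as a block. Added after seeing the data were fits without the 2 E16.5 knockout arrays (replicates 1 and 4) with high hybridization controls, fits without each other pair of E16.5 knockout arrays, fits with the bioB hybridization control or the Gapdh 3' minus 5' difference as a covariate, and the list tests without each array in turn. The agreement between probe sets of a gene was also computed after seeing the data.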

Results

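Expression was measured in whole ovaries of control and Coup-tfII (Nr2f2) knockout embryos at E14.5 (3 control and 3 knockout arrays) and E16.5 (4 control and 4 knockout arrays). Median signal per array was 90.0 to 102 at E14.5 and 118 to 136 at E16.5. Correlations of log2 values between arrays, across probe sets, were 0.969 to 0.982 within a group and 0.857 to 0.877 between stages. The 9 probe sets of 3 Y-linked genes had a highest signal of 48.1 over all arrays, while Xist had a lowest signal of 5281. No arrays held identical values.

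Nr2f2, the targeted gene, had 6 probe sets, 5 of which had all E16.5 knockout arrays below all controls and 3 of which passed as lower. The brightest, which stood for Nr2f2 in the gene tests, had a log2 change of -0.79 ± 0.22 (SE) at E16.5 and did not pass (limma adjusted p = 0.0753). All its knockout arrays lay below all controls, with 4332 ± 467 (SD, n = 4) in controls and 2534 ± 575 (SD, n = 4) in knockouts. The probe set with 1974 ± 185 (SD, n = 4) in E16.5 controls had 321 ± 60.6 (SD, n = 4) in knockouts, and it fell by 2.57 ± 0.45 on the log2 scale (limma adjusted p = 0.0135 over all probe sets). The probe set with 974 ± 72.4 (SD, n = 4) in controls had 329 ± 138 (SD, n = 4) in knockouts and a log2 change of -1.60 ± 0.21 (limma adjusted p = 0.00295), and a dim one, below the filter, fell from 92.6 to 16.0 (limma adjusted p = 0.0448). At E14.5 no Nr2f2 probe set passed in limma: the brightest had a log2 change of -0.67 ± 0.25 (adjusted p = 0.444), from 377 ± 143 (SD, n = 3) to 225 ± 60.9 (SD, n = 3), and the smallest unadjusted p was 0.0145. On the probe set with 1974 in E16.5 controls, E14.5 control replicate 1 had 19.3. The other E14.5 controls had 350 and 207 and the knockouts 34.6 to 79.1. On the dim one it had 16.1, against 176 and 98.3 in controls and 25.7 to 40.7 in knockouts. On the brightest it had 217, against 493 and 422, and 155 to 267. On the probe set with 974 in E16.5 controls it lay above all knockouts. Whether that array was labelled correctly was not tested. A probe set outside the deleted part checks nothing, and which probe sets lie inside it is not given in the sources used here. Wt1, whose locus drives the recombinase, had log2 changes of -0.23 ± 0.15 at E14.5 and -0.37 ± 0.13 at E16.5 (limma adjusted p = 0.694 and 0.143). At E16.5 all its knockout arrays lay below all controls, with 4220 ± 200 (SD, n = 4) in controls and 3268 ± 143 (SD, n = 4) in knockouts. Adjusted over the list of Nr2f2 and Wt1 alone, 2 of 2 were lower at E16.5 and 1 of 2 at E14.5.

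**Figure D1:**
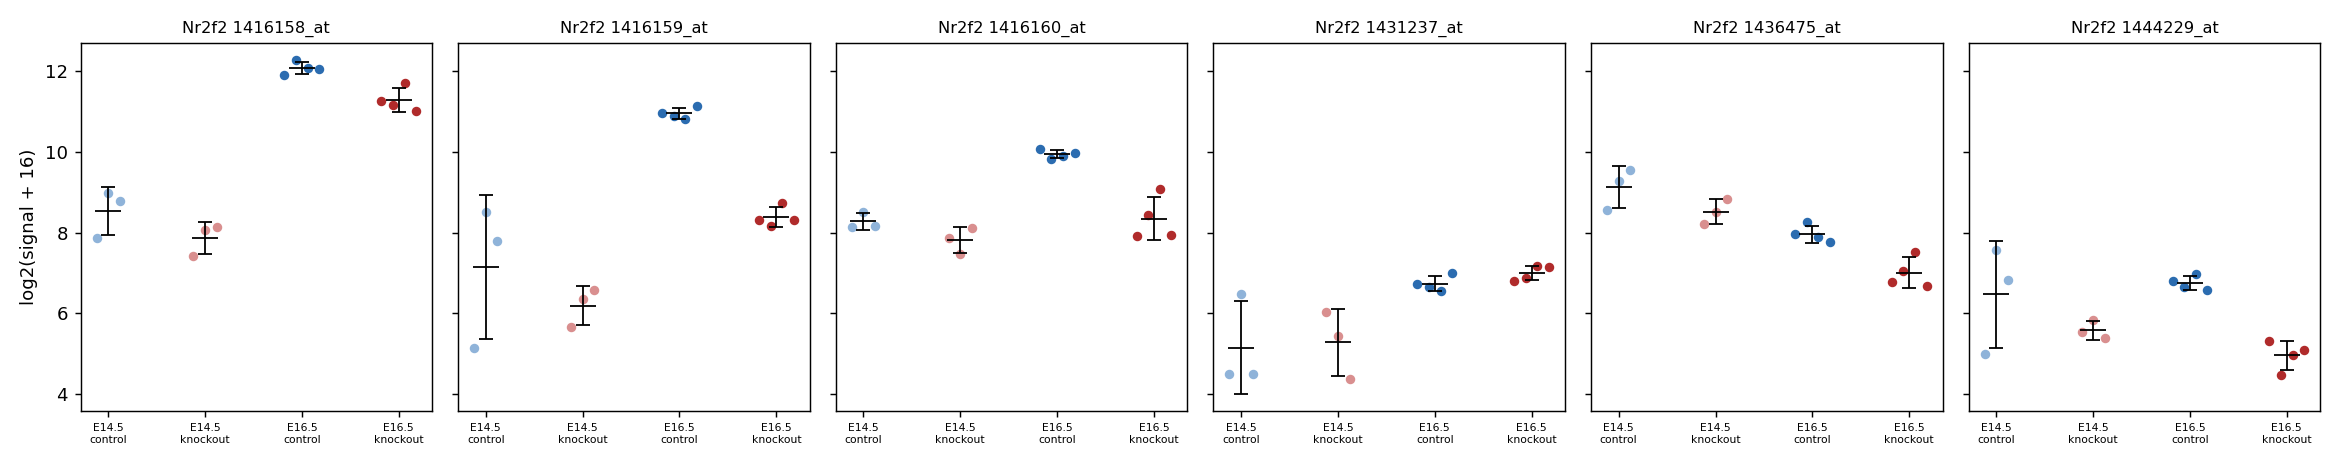
Each panel shows 1 of the 6 Nr2f2 probe sets as log2(signal + 16) on the vertical axis for the 4 groups, with a point per array and bars for the mean and SD. At E16.5 the knockout arrays lie below all controls in 5 panels, and in the fourth panel from the left they do not.

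Knockout against control at E14.5 asked how expression differed 2 days after the last tamoxifen dose. Pmaip1, a p53-induced promoter of apoptosis, rose by a log2 change of 2.02 ± 0.35 (SE, n = 3 per group). Pram1 rose by 1.71 ± 0.29, the metal-binding Mt1 by 0.99 ± 0.17, B2m, the light chain of class I histocompatibility molecules, by 0.76 ± 0.12, and the glypican Gpc3 by 0.63 ± 0.11. Control signals of Pram1 (8.10 ± 2.06, SD, n = 3) and Pmaip1 (35.6 ± 22.6) lay below the filter level of 62.0, so the size of these changes depends on the pseudocount (0.84 and 1.35 with 64, where neither passed). These were the 5 genes of 12406 that passed, each at a limma adjusted p of 0.0473; none fell, and 1061 genes had an unadjusted p under 0.05. The groups did not overlap for these 5 genes and for 12.7% of all genes. Chance gives 10%. Leaving out control replicate 1, 2 or 3 gave 23, 0 or 0 genes, and leaving out knockout replicate 1, 2 or 3 gave 1, 0 or 179. No gene passed with quantile normalization, median centring, a pseudocount of 64, the 60th percentile filter, no trend in eBayes, or the arrays of this stage alone, nor with the Gapdh 3' minus 5' difference as a covariate, chosen after seeing the data.

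Among the gene lists at E14.5, the p53 targets shifted up (camera adjusted p = 1.29e-08, and adjusted p = 0.0237 with an estimated correlation), the only list of this comparison whose call held with an estimated correlation. Of 11 measured members 1 rose over all genes and 7 rose adjusted over the list alone. Examples, chosen after their values were seen, were Eda2r (1.39 ± 0.28, SE), the cyclin Ccng1 (1.02 ± 0.20) and the cell cycle inhibitor Cdkn1a (0.64 ± 0.18). Members that did not rise detectably were Mdm2 (-0.0022 ± 0.15), Sesn2 (0.04 ± 0.31), Aen (0.12 ± 0.15) and Trp53inp1 (0.26 ± 0.16). The extracellular matrix list shifted up (camera adjusted p = 3.70e-07; adjusted p = 0.505 with an estimated correlation), with 0 of 22 members past over all genes and 2 higher adjusted over the list alone. All 22 changes were positive, and Fbln2 had 1.23 ± 0.36. The mean log2 change of the list was 0.56, and 0.25 without knockout replicate 2. The coelomic and surface epithelium list shifted up (camera adjusted p = 0.0139; adjusted p = 0.505 with an estimated correlation), with 0 of 10 members past and 2 higher adjusted over the list alone. Krt19 had 1.44 ± 0.28. The immediate early and stress list shifted up (camera adjusted p = 0.00274; adjusted p = 0.505 with an estimated correlation), with 0 of 12 members past and 0 adjusted over the list alone. The early germ cell and pluripotency list shifted down (camera adjusted p = 0.00206; adjusted p = 0.505 with an estimated correlation), with 0 of 9 members past, and 4 lower and 1 higher adjusted over the list alone. Sox2 had -2.76 ± 0.97 and Sall4 -2.03 ± 0.70. The general germ cell list shifted down (camera adjusted p = 0.0467; adjusted p = 0.599 with an estimated correlation), with 0 of 12 members past and 0 adjusted over the list alone. Dazl had -0.44 ± 0.17. Stra8, required for entry into meiosis, had -1.98 ± 0.73 (limma adjusted p = 0.432), and its list did not pass (camera adjusted p = 0.0640).

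Some of these list calls at E14.5 rested on single arrays. The early germ cell list was lost without control replicate 1 (camera adjusted p = 0.0653) or knockout replicate 1 (0.0778), and the general germ cell list without control replicate 1 (0.0612), control replicate 3 (0.257) or knockout replicate 2 (0.389). The general germ cell list was also lost with the Gapdh covariate (0.0732). The coelomic list was lost without control replicate 2 (0.0577), knockout replicate 2 (0.0812) or knockout replicate 3 (0.0719), and the immediate early list without knockout replicate 2 (0.0812). The p53 and extracellular matrix lists passed without any 1 array of this stage. Mean log2 changes of the lists moved as well. That of the early germ cell list was -1.09, and -0.70 or -1.77 without knockout replicate 1 or 3. That of the general germ cell list was -0.18, and -0.11 without control replicate 3, -0.057 without knockout replicate 2 and -0.28 without knockout replicate 3. Without knockout replicate 2 the coelomic list went from 0.48 to 0.30 and the immediate early list from 0.33 to 0.18. In fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, 2 lists passed: the p53 targets (adjusted p = 0.00124) and the mesonephric and duct epithelium list (adjusted p = 0.0348; camera adjusted p = 0.110). The median, mean and test differed in sign for the steroid synthesis, hedgehog and mesonephric mesenchyme lists, none of which passed.

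Knockout against control at E16.5 asked the same question 4 days after the last dose. Among genes whose arrays did not overlap, those with the highest values were Cga, the common subunit of glycoprotein hormones (log2 change 1.99 ± 0.26, SE, n = 4 per group), Hdc, which makes histamine (1.80 ± 0.35), Ephx1, an epoxide hydrolase (1.79 ± 0.18; limma adjusted p = 0.000138), and the growth factor Vegfd (1.61 ± 0.33), leaving out clone symbols. Among the tested genes without overlap, those that fell most were Ajap1 (-2.24 ± 0.34), the collagen Col25a1 (-1.60 ± 0.27) and the basement membrane gene Frem1 (-1.58 ± 0.15, limma adjusted p = 6.99e-05). Ret, too dim to be tested, had -1.76 ± 0.33 in the fit without a filter (limma adjusted p = 0.0184). Mgarp, Col9a1, Ly6d, Hsd3b1 and the fatty acid binding Fabp4 and Fabp3 also rose, by 1.53 to 1.58. Ctxn3, Lbhd2, Lrfn5, Wnt5a, Amph, Pdgfra and Trpc6 also fell, with log2 changes of -1.46 to -1.22. Cga had a control signal of 9.69 ± 5.26 (SD, n = 4), below the filter level, so its size and rank depend on the pseudocount (1.02 ± 0.16, SE, with 64). Control signals of Mgarp, Col9a1, Ly6d, Mc2r, S100b and Nr4a1 and the knockout signal of Lrfn5 also lay below it, and Ly6d and Nr4a1 did not pass with 64 (limma adjusted p = 0.0629 and 0.0557). Outside the rule, Dpt (2.27) and Cwc22 (2.24) rose further, but their groups overlapped. In all, 176 of 12406 genes passed in limma, 120 higher and 56 lower. The groups did not overlap for 171 of these and for 10.4% of all genes. Chance gives 2.86%.

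**Figure D2:**
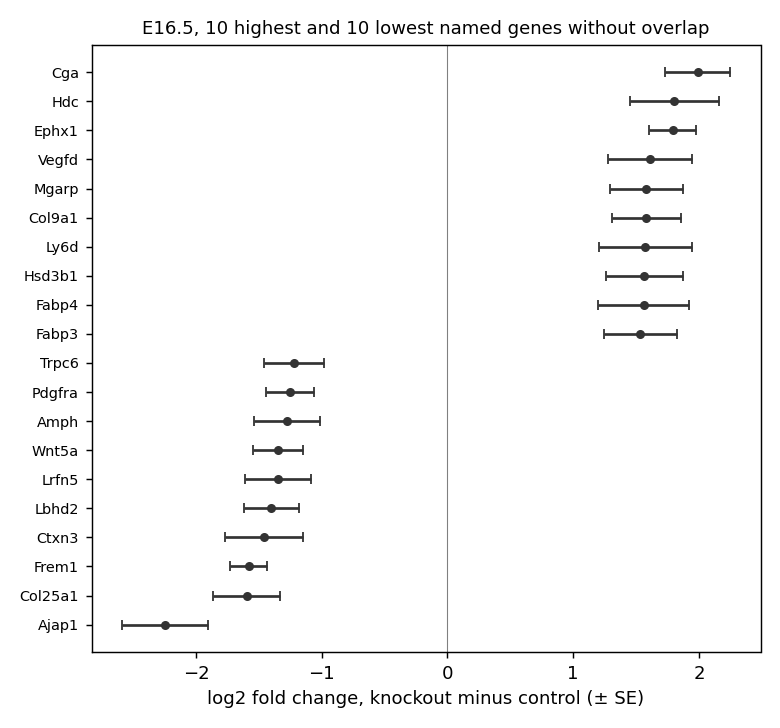
The horizontal axis gives the log2 fold change of knockout minus control at E16.5 with its SE, for the 10 highest and 10 lowest genes past the threshold whose arrays did not overlap, leaving out clone symbols. Cga, whose control signal lay below the filter level, lies at 1.99 and Ajap1 at -2.24.

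The number of genes at E16.5 moved with single arrays. It was 83, 78, 80 and 100 without control replicate 1, 2, 3 and 4, and 43, 494 and 102 without knockout replicate 1, 2 and 4. The count without knockout replicate 3 lay between 43 and 494. Of 37 named genes past the threshold, 14 passed without knockout replicate 1, among them Cga, Ephx1, Frem1, Wnt5a, Pdgfra, Mc2r, Fgf2, Ccng1, Cdkn1a and Zmat3, and 23 did not, at limma adjusted p of 0.0530 to 0.140. Knockout replicates 1 and 4 had bioB hybridization control signals of 10843 and 18373, against 4555 to 6397 on the other E16.5 arrays. Of 14 measures of the arrays, 2 separated all E16.5 knockouts from all controls. The log2 difference of Gapdh 3' minus 5' signal was 1.75 ± 0.07 (SD, n = 4) in controls and 1.37 ± 0.31 (SD, n = 4) in knockouts, and the signal of the middle probe set of the dap control was 466 ± 52.7 and 663 ± 111. The 3' probe set of dap did not separate them (1792 ± 174 and 1668 ± 257). Each of the 2 measures had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allow (adjusted over the measures, 0.160). With the Gapdh difference as a covariate, chosen after seeing the data, 18 genes passed, 17 of them among the 176. All 176 kept their sign with it, with a median size of the log2 change of 0.80 against 0.90 and a median SE of 0.23 against 0.18. Without both knockout replicates 1 and 4, an alternative chosen after seeing the data, 16 genes passed, of which 13 were among the 176. They included Cga, Ephx1, Frem1, Wnt5a, Ccng1, Eda2r and Cdkn1a, and no other of the 37 named genes. Dpt, outside the rule, also passed. Dpt was lost without control replicate 1, 3 or 4 or knockout replicate 1, and Cwc22 without any of these, knockout replicate 3 or knockout replicate 4.

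Of the interstitial genes at E16.5, Wnt5a (-1.34 ± 0.20, SE) and Pdgfra (-1.25 ± 0.19) fell, whereas their list did not shift (camera adjusted p = 0.717; 0 higher and 2 lower of 16 over all genes, 2 higher and 3 lower adjusted over the list alone). Gli2, a transcription factor of hedgehog signalling, fell (-0.85 ± 0.18), as did Fgf2 (-0.87 ± 0.15). The hedgehog list (camera adjusted p = 0.0969; 0 higher and 1 lower of 8, 0 and 1 adjusted over the list alone) and the FGF list (camera adjusted p = 0.927; 0 higher and 1 lower of 12, 2 and 2 adjusted over the list alone) did not pass. Of the endothelial genes Plvap rose (1.18 ± 0.21) and Tek fell (-0.68 ± 0.15), and the list did not pass (camera adjusted p = 0.198; 1 higher and 1 lower of 20, 2 and 1 adjusted over the list alone). Hsd3b1, a steroid synthesis enzyme, rose (1.57 ± 0.30), as did Hao2 (1.49 ± 0.27) and the corticotropin receptor Mc2r (1.46 ± 0.23), 2 of the 3 measured adrenal cortex genes. The third, Mrap, had 0.90 ± 0.25, and all 3 were higher adjusted over the list alone. The steroid synthesis list did not pass (camera adjusted p = 0.523; 1 higher and 0 lower of 7, 3 and 1 adjusted over the list alone). At E14.5 Hsd3b1, Hao2 and Mc2r had 1.02 ± 0.35, 1.03 ± 0.31 and 0.71 ± 0.27 and did not pass. Star had a signal of 286 ± 77.9 (SD, n = 4) in controls and 338 ± 51.3 (SD, n = 4) in knockouts, and Cyp11a1 had 168 ± 42.2 and 106 ± 28.7. The muscle filament gene Des (1.17 ± 0.25), the glial S100b (1.04 ± 0.22) and Aldh1a3, which makes retinoic acid and lies near the targeted locus (0.72 ± 0.16), rose as well. Their lists went both ways adjusted over the list alone: 2 higher and 2 lower of 7 for smooth muscle (camera adjusted p = 0.930), 1 and 1 of 3 neural and glial genes, too few for camera, and 2 and 1 of 13 for retinoic acid (camera adjusted p = 0.930). The glial Fabp7 had -1.26 ± 0.31 (limma adjusted p = 0.0509).

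The p53 targets shifted up at E16.5 too (camera adjusted p = 3.83e-06; adjusted p = 0.0737 with an estimated correlation). Of 11 members 4 rose over all genes and 8 adjusted over the list alone: Ccng1 by 1.24 ± 0.17 (SE), Eda2r by 1.21 ± 0.24, Cdkn1a by 1.16 ± 0.16 and Zmat3 by 0.85 ± 0.14 led. Pmaip1, which rose at E14.5, had 0.09 ± 0.30. Perp had -0.03 ± 0.24 and Mdm2 0.24 ± 0.13. The macrophage and leukocyte list shifted up (camera adjusted p = 0.00700; adjusted p = 0.911 with an estimated correlation), with the complement gene C1qb (0.82 ± 0.20) higher of 15 and 3 adjusted over the list alone. The coelomic and surface epithelium list shifted up (camera adjusted p = 0.0178; adjusted p = 0.565 with an estimated correlation), with Krt19 (1.24 ± 0.25) and Upk1b (1.01 ± 0.24) higher of 10 and 5 adjusted over the list alone. The immediate early and stress list shifted up (camera adjusted p = 0.0461; adjusted p = 0.911 with an estimated correlation), with Nr4a1 (0.97 ± 0.22) higher of 12 and 2 adjusted over the list alone. The pre-granulosa list shifted down (camera adjusted p = 0.0461; adjusted p = 0.834 with an estimated correlation), with 0 of 20 members past and 4 lower adjusted over the list alone. Foxl2, a determinant of granulosa cells, had -0.83 ± 0.20 (limma adjusted p = 0.0504).

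Among the lists past at E16.5, only the p53 targets passed with the Gapdh difference as a covariate (camera adjusted p = 1.40e-07), and the others had 0.0702 to 0.111. No list call at E16.5 held with an estimated correlation, and in fry only the p53 targets passed (adjusted p = 0.00181). The p53 list passed in camera without any 1 array, at a largest adjusted p of 0.000312. Without knockout replicate 1 the macrophage (camera adjusted p = 0.0754), coelomic (0.0522), immediate early (0.0988) and pre-granulosa (0.0522) lists were lost, and the mean log2 change of the macrophage list went from 0.41 to 0.23. The immediate early list was also lost without control replicate 3 (0.104) or 4 (0.124) or knockout replicate 2 (0.0534) or 3 (0.109). The pre-granulosa list was also lost without control replicate 1 (0.0930) or 2 (0.121) or knockout replicate 2 (0.0598) or 4 (0.0974). The median, mean and test differed in sign for the interstitial, smooth muscle, duct epithelium, mesonephric mesenchyme, FGF, WNT and BMP lists, none of which passed.

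**Figure D3:**
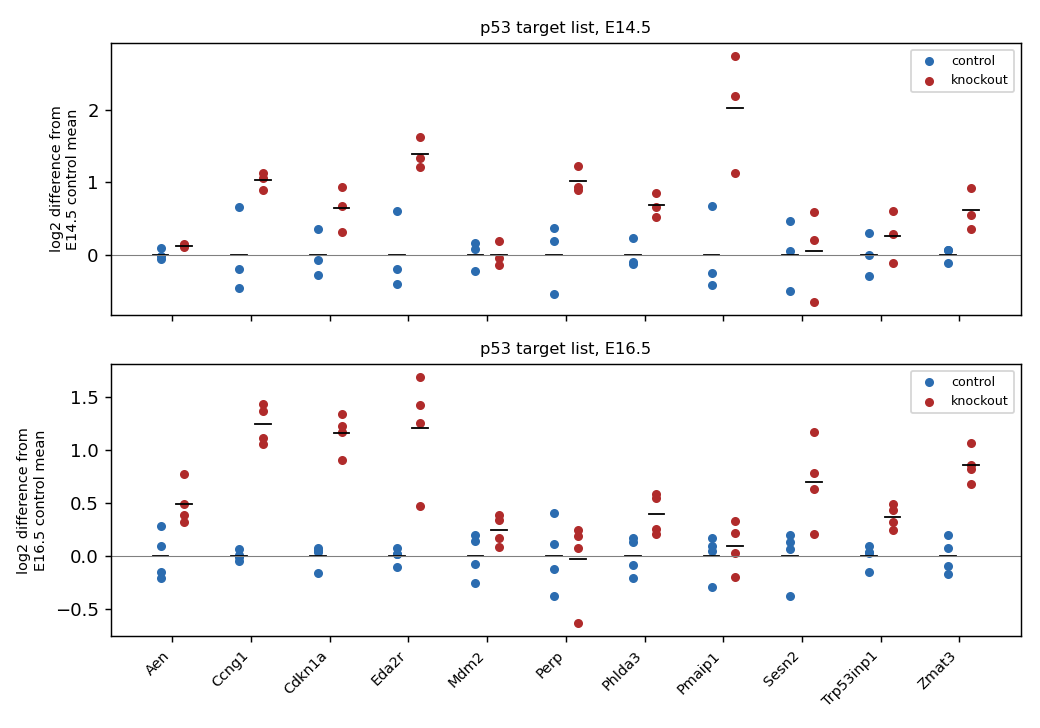
The vertical axes give the log2 difference of each array from the mean of the controls of its stage for the 11 measured p53 targets, with a point per array and a line at each group mean. Ccng1, Eda2r, Cdkn1a and Zmat3 lie higher in all knockout arrays than in all controls at E16.5.

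Whether the knockout effect differed between stages was tested directly. The early germ cell and pluripotency list passed in camera (adjusted p = 0.000280, and adjusted p = 0.821 with an estimated correlation). Of its 9 members 0 passed over all genes and 5 adjusted over the list alone. All 9 differences were positive, that is, less negative or more positive at E16.5. The p53 list did not differ detectably (camera adjusted p = 0.985), with 7 positive and 4 negative differences and 1 lower adjusted over the list alone. Its median (0.22) and mean (-0.10) differed in sign, as did median, mean or test for the Sertoli, mesonephric mesenchyme, cell cycle, WNT, cholesterol and immediate early lists, none of which passed. No single gene passed in limma (smallest adjusted p = 0.398; 1105 genes at an unadjusted p under 0.05), and the smallest p values belonged to Shroom4 (difference of log2 changes 0.84 ± 0.18, SE), Tgfb2 (-1.09 ± 0.23) and Hmgn3 (-0.93 ± 0.20). Without E14.5 knockout replicate 3, 30 genes passed, and without E16.5 control replicate 2, 1 gene. Across 12406 genes, which are not independent replicates, the log2 changes of the stages had r = 0.222 and rho = 0.182. Of the 176 genes past at E16.5, 148 (84.1%) had the same sign at E14.5, against 55.9% of all genes. B2m passed at both stages, where 0.0484 genes would if passing were independent (Fisher's exact test, one-sided p = 0.0474). That p decides little, since it rests on 1 gene and both comparisons share the estimate of spread of each gene. B2m lies on chromosome 2, among the 100 tested genes on a side of Wt1, the Cre locus.

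E16.5 was set against E14.5 within each genotype, and the values are differences between sets of arrays that cannot be told apart from stage. In controls H1f4 (log2 difference 7.04 ± 0.21, SE), Cd247 (6.88 ± 0.29) and the globin Hba-a2 (6.60 ± 0.41) were measured highest at E16.5 relative to E14.5, and Pik3cd (-9.18 ± 0.48), the ribosomal protein gene Rpl37 (-6.52 ± 0.32) and the embryonic globin Hbb-y (-5.73 ± 0.45) lowest. These sizes and ranks depend on the pseudocount wherever the signal of a stage lay below the filter level. Of 22 meiotic prophase genes in controls 2 were higher and 19 lower, Stra8 (-5.13 ± 0.68) among them, and 2 and 20 adjusted over the list alone (camera adjusted p = 0.00282; adjusted p = 0.959 with an estimated correlation). In knockouts 1 was higher and 18 lower, likewise adjusted over the list alone (camera adjusted p = 0.00751; adjusted p = 0.893 with an estimated correlation). In limma 7993 genes passed in controls (44.3% higher) and 7547 in knockouts (44.4% higher). With median centring 26.5% and 25.6% of those past were higher. Probe sets of a gene did not measure these differences alike, a check made after seeing the data. Of 4210 genes past in controls with at least 2 probe sets above the filter, the 2 brightest had the same sign in 56.9%, and in knockouts in 56.7% of 4033, against 91.8% of 73 for knockout against control at E16.5. For these genes the disagreement argues against stage as the whole cause of the differences. Nr2f2 itself went from 377 to 4332 in controls on its brightest probe set and from 568 to 236 on another. Among control probe sets, bioB was 1429 to 1940 at E14.5 and 4555 to 18373 at E16.5, and the log2 difference of Gapdh 3' minus 5' signal was -0.31 ± 0.13 (SD, n = 6) and 1.56 ± 0.29 (SD, n = 8).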

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

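Tests chosen only after the result was seen were those of adrenal tissue, of Cre activity, of the 4 genes near the loci, of pairs of E16.5 knockouts left out or picked from, of the Gapdh covariate, of the p53 list and of Hsd3b1, Hao2 and Mc2r without the 2 arrays, and of the splits for the knockout gene counts at both stages.

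Other splits of the arrays were refitted. For knockout against control at E16.5, 1 of 35 splits gave as many genes as the real 176, the real one itself, and the highest other gave 7. A share of 1 of 35 is the smallest that these splits allow. It argues against chance for the count and does not exclude it. For E14.5, 3 of 10 splits gave as many as the real 5 and the highest other gave 6; 10 splits are too few for a share under 0.05. For stage, 1 of 35 splits reached the real 7993 in controls (highest other 4791) and 1 of 35 the real 7547 in knockouts (highest other 4445). Both of these highest other splits reversed the stages of all arrays but 1 E16.5 array. Their counts thus hold the difference between stages and are not what chance gives. The stage shares of 1 of 35 argue against chance but not against the array difference between stages. For the difference between stages 100 of 100 splits drawn gave at least the real 0, and the highest other gave 138. That split exchanged 4 E14.5 arrays, control replicates 2 and 3 against knockout replicates 2 and 3, and kept every E16.5 array in its group. With most E14.5 labels reversed, its contrast added part of the E14.5 knockout effect to that at E16.5. Its count therefore does not stand for chance alone. How many of its genes rest on this was not tested. For the number of gene lists past the threshold, chance is not excluded at E16.5, where 18 of 35 splits gave at least the real 5 and the highest other gave 10. Nor is it for the difference between stages, where 94 of 100 gave at least the real 1 and the highest other gave 12. For lists at E14.5, 4 of 10 gave at least the real 6 and the highest other gave 9, and 10 splits are too few for a share under 0.05.

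At E16.5, 16 genes passed without knockout replicates 1 and 4, against 4 to 106 without 4 other pairs of knockouts and 1830 without replicates 2 and 3, so leaving out other pairs also lowered the count, and it was highest with these 2 arrays as the only knockouts. The 176 genes, picked with all arrays, kept their sign without the 2 arrays, with a median size of 0.77 against 0.90 and standard errors 1.17 times as large. Genes were then picked from these 2 arrays against 2 controls and looked up in the other knockouts against the other 2 controls: over 6 splits of the controls, 77.6% of the top 200 genes had the same sign (range 68.0% to 84.5%), against 58.6% of all genes, but their size was 0.206 times that in the 2 arrays (medians of 0.18 to 0.27 against 1.02 to 1.13), against 0.539 to 0.664 times for genes picked from other pairs; the lowest split missed the bound of 75% set beforehand, so a part played by array quality cannot be told apart from a weaker effect in the other arrays. With the Gapdh difference as a covariate 18 genes passed. Over the 176 genes the median standard error grew from 0.18 to 0.23, and the median size fell from 0.90 to 0.80. How much each lowered the count was not tested. The log2 changes of the 176 genes were a median of 0.936 times those without it (quartiles 0.813 and 1.08). These genes were picked on the same arrays by the fit without the covariate. The ratio therefore does not decide how far that difference is a cause, which stays open. DNA of another strain linked to the Nr2f2 and Wt1 loci is argued against as the whole cause, since 2.27% of the genes lay among the 100 tested genes on each side of them, under the bound of 10%, but for the 4 genes there, B2m, Aldh1a3, Rasgrp1 and Them7, it stays open.

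The p53 targets were higher in knockouts at both stages (adjusted p = 0.0237 at E14.5 and adjusted p = 0.0737 at E16.5 with an estimated correlation, so the call at E16.5 is lost). At E16.5 the mean log2 change was 0.61, and 0.62 without the 2 arrays (camera adjusted p = 4.05e-08) and 0.64 with the Gapdh covariate (camera adjusted p = 1.40e-07), which argues against these array differences as the whole cause. With the array mean of the immediate early list as a covariate, the larger camera p of the stages was 5.05e-06. The mean log2 change was then 0.57 against 0.71 at E14.5 and 0.47 against 0.61 at E16.5. The size that stayed argues against handling stress, as far as that list measures it, as the whole cause, and leaves a part open. As a set, 1 of 35 splits at E16.5 gave a camera p as small as the real 1.53e-07, the real one itself. That is the smallest share that 35 splits allow, and another split came close at 3.04e-07. Chance is therefore not excluded, and a small camera p alone decides little here. Tamoxifen alone was given to both groups, but loss of Nr2f2 cannot be told apart from Cre activity, since 0 control arrays have labels that give Cre; either may raise these genes.

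Hsd3b1, Hao2 and Mc2r, singled out after their values were seen, were higher at E16.5 by a mean log2 change of 1.51 ± 0.20 (SE). Adrenal tissue in the knockout samples could bring such genes and cannot be told apart from a change in the ovary, since adrenal genes went both ways. Star, Cyp11a1 and Cyp21a1 had a mean log2 change of -0.0425 (95% limits -0.49 to 0.41), below the bound of 0.75. Of these, Cyp11a1 was lower in knockouts, with -0.595 ± 0.23 (limma unadjusted p = 0.0198). Star had 0.25 ± 0.20 and the dim Cyp21a1 0.21 ± 0.46. Mrap (90.4 in controls, 181 in knockouts), by contrast, had 0.90 ± 0.25 (limma unadjusted p = 0.00227). The dim Cyp11b2 (5.68 and 19.9) had 0.73 ± 0.26 (limma unadjusted p = 0.0115). Without the 2 arrays the mean of the 3 genes was 1.49 ± 0.24, so the calls were lost with fewer arrays and not with a smaller fold. A change in steroid-synthesising cells of the ovary stays open and was not tested.

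Of 136 groups of 4 arrays examined, 8 held an array far from the other 3, where chance gives about 1 in 20. Lrfn5 in E16.5 knockout replicate 3 was 113 against 38.5 to 43.0 (gap over range 0.909), and Pdgfra in the same array 1669 against 1127 to 1194 (0.854). Cdkn1a in control replicate 4 was 391 against 453 to 464 (0.849), and Nr4a1 in knockout replicate 2 was 57.2 against 110 to 122 (0.860). The mean log2 value of the interstitial list in control replicate 2 was 10.38 against 10.16 to 10.18 (0.903), and that of endothelial genes in control replicate 1 was 8.81 against 8.70 to 8.71 (0.879). In knockout replicate 1 the smooth muscle mean was 9.71 against 9.23 to 9.29 (0.868) and the coelomic epithelium mean was 10.10 against 9.48 to 9.55 (0.894).

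The early germ cell list passed in camera for the difference between stages (adjusted p = 0.000280, and adjusted p = 0.821 with an estimated correlation). It was down at E14.5 (adjusted p = 0.505 with an estimated correlation) and not past the threshold at E16.5 (camera adjusted p = 0.128). At E14.5 its mean log2 difference from controls was -1.88, -1.66 and 0.26 in knockout replicates 1, 2 and 3. Replicate 3 thus did not share the fall. Outside the named genes, 25 of 3750 probe sets with no or several gene symbols passed at E16.5, 14 higher and 11 lower.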

How the results depend on the processing

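The fits without the 2 arrays with high bioB or another pair of E16.5 knockouts, those with bioB or the Gapdh difference as a covariate, and the list tests without each array, were chosen after seeing the data. Over all alternatives, values of named genes kept direction and side of the threshold 3771 times, lost the call 286 times, gained it 42 times, turned direction with no call before or after 20 times, and turned direction with a call 9 times. Lists that passed in any comparison kept their side 279 times, lost the call 52 times and gained it 21 times. The E14.5 count of 5 became 0 with a pseudocount of 64, quantile normalization, median centring, the 60th percentile filter, no eBayes trend or only the arrays of that stage, 9 without a filter, 11 with array weights and 202 at unadjusted p under 0.01 and a fold of 1.5. Leaving out 1 array gave 0 to 179, and 0 of the 5 genes were kept in all 6 fits. The E16.5 count of 176 became 279 with quantile normalization and 425 at the unadjusted threshold. Leaving out 1 array gave 43 (knockout replicate 1) to 494 (knockout replicate 2), and 39 genes were kept in all 8 fits. At E16.5, 16 genes passed without the 2 arrays with high bioB and 20 with bioB as a covariate; fewer arrays and a covariate also lower the power. Without knockout replicates 1 and 2, 1 and 3, 2 and 3, 2 and 4, or 3 and 4 the count was 4, 37, 1830, 106 or 35. With the Gapdh covariate it was 18, and 0 at E14.5, while median sizes were 0.80 against 0.90 and 0.997 against 0.992, with 3 lists at E16.5 and 4 for the difference between stages. The stage counts became 18095 in controls and 17338 in knockouts with every probe set tested, since 27022 probe sets in place of 12406 genes were then tested, and were 7274 to 7626 and 6934 to 7434 without 1 array. Median centring moved the share of higher calls from 44.3% to 26.5% in controls (2257 higher, 6251 lower) and from 44.4% to 25.6% in knockouts (2082 higher, 6065 lower), with median log2 changes of all genes of -0.43 and -0.41 against -0.09 and -0.08; quantile normalization gave medians of -0.21 and -0.20. With the mean of probe sets, genes of the stage comparison in controls turned direction: Dnajc17 0.30, Kitl 1.57, Igf1 0.40, Gas1 1.48, Taf4b 0.25, Laptm5 -0.0285, Ccng1 0.33, Sesn2 0.0434 and Xist 0.0378, as probe sets of a gene disagreed. The difference between stages gave 1 gene without a filter, 203 at the unadjusted threshold and 0 to 30 without 1 array. Lists past the threshold fell from 6 to 1 with an estimated correlation and 2 with fry at E14.5, from 5 to 0, 1 and 3 (quantile normalization) at E16.5, and from 1 to 0 and 0 for the difference; without the 2 arrays 8 passed at E16.5, and without 1 array 3 to 7, 1 to 6 and 1 to 4. The correlation of the stages was 0.167 to 0.232. Replicate numbers did not pair all arrays: 1 of 3 same-numbered correlations of deviations from the group means at E14.5 and 2 of 4 at E16.5 were over 0.1, and not every array correlated best with its own number. At E16.5 control and knockout replicate 4 had r = 0.430 and replicate 1 had 0.192, so pairing of some arrays stays open. With the replicate block the counts were 9 at E14.5, 293 at E16.5, 0 for the difference, 7964 and 7501 for the stages, and 12, 4 and 3 lists. Where no reason is given, the cause was not tested. Genes near the filter level of 62.0 are limited by signal over background.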

Other observations

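Genes and arrays in this part were singled out only after the values were seen, and no test was added. Among the 39 genes past the threshold at E16.5 in every fit without 1 array, several lay outside the rule for named genes and were chosen after their values were seen. Bmp5, a bone morphogenetic protein, was higher in knockouts by a log2 change of 1.40 ± 0.22 (SE; limma adjusted p = 0.00533), Thbd, the endothelial thrombin receptor thrombomodulin, by 1.12 ± 0.15 (adjusted p = 0.00241) and Capn6 by 1.29 ± 0.20 (adjusted p = 0.00513). Grk5, a kinase of G protein-coupled receptors, was lower by a log2 change of -0.79 ± 0.13 (adjusted p = 0.00715), and Dact1, a regulator of WNT signalling, by -0.86 ± 0.15 (adjusted p = 0.00977). At E14.5 the log2 changes of Bmp5, Thbd, Capn6, Grk5 and Dact1 were 0.21, 0.66, 0.98, -0.44 and -0.56. Without the 2 E16.5 knockout arrays with high bioB, Bmp5 and Dact1 no longer passed, and Thbd, Capn6 and Grk5 did.

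The E14.5 knockout arrays differed from each other in Stra8, Sall4 and Dmrt1. Stra8 signal was 1171, 566 and 5679 in knockout replicates 1, 2 and 3, and 8166, 5351 and 5443 in the controls. Sall4 was 37.1, 51.8 and 638 in the knockouts and 1068, 289 and 465 in the controls, and Dmrt1 was 61.8, 62.7 and 712 against 662, 393 and 442. Sycp3, of the meiotic chromosome axis, was 25000, 22670 and 20160 in the knockouts and 18330, 19750 and 24490 in the controls.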
